A study of Mus musculus with 2 samples.

How the data were processed

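MicroRNA sequencing, which reads RNA fragments under 30 nucleotides long per the labels, was used to measure microRNAs in kidneys of mouse embryos at embryonic day 16.5. Per the labels, the strain was B6NCrl, embryos of both sexes were pooled, and the 2 libraries were biological replicates 1 and 2 of the same tissue and age. Replicate 2 came from 41 embryos, and the number pooled for replicate 1 is not given in the sources used here. The labels give the libraries separate tissue sample records and the same donor record, so the SDs, the BCV and the p-values measure the spread between these libraries, part of which may be technical. The series holds 1 group, so no contrast between conditions exists, and every test between libraries compares these 2 pools and not conditions.

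The deposited tables hold raw counts of reads per annotated microRNA gene on assembly mm10 with genome annotation M4, per the text files that accompany them. The aligner, the counting program and the adapter trimming are not given in the sources used here. Each deposited table has 3 columns of counts and no column names. In all 1973 gene rows the first column equals the sum of the other 2, which are therefore taken as either strand, the strand of the gene and the opposite strand. The strand of the gene was used throughout, because it held 5317669 and 7128703 reads in replicates 1 and 2 against 116411 and 163088 on the opposite strand.

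Each deposited table opens with 4 rows that name no gene: unmapped reads, reads mapping to several places, reads in no gene and ambiguous reads. They held 55.2% of the 11877442 reads of replicate 1 and 51.5% of the 14706415 reads of replicate 2, and were kept out of library sizes and tests. Unmapped reads made up 20.5% and 21.9%, reads mapping to several places 28.0% and 25.3%, and reads in no gene 6.70% and 4.32%. Reads mapping to several places are in no gene row. A microRNA made from identical copies of a gene is therefore undercounted, and its level is uncertain. To mark such genes, the precursor sequences of GENCODE M21 were compared, and a gene was said to share sequence when a stretch of 18 nt occurred in another microRNA gene. Mature microRNA sequences were not used here.

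Gene symbols, coordinates and overlaps with other genes were taken from GENCODE M21 on GRCm38, the assembly also called mm10, by Ensembl identifier without version. Of the 1973 rows, 1894 matched, and the 79 unmatched rows held 3 reads over both libraries. Another 308 microRNA genes of that annotation have no row in the tables used here and were not analysed here.

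Counts per 1000000 (CPM) were computed from the total of sense reads in gene rows. At this depth 3 reads, the upper limit allowed by a count of 0, equal 0.564 CPM in replicate 1 and 0.421 CPM in replicate 2. Shares of reads are given with exact Clopper-Pearson 95% intervals where a single library is described. Intervals and floors cover counting error only, since reads without molecular identifiers are not independent molecules. A gene was called detected at 1 CPM or more in both libraries. Correlations across genes used log2(CPM + 1), and genes are not independent replicates, so they carry no p-value. The smallest fold between a pair of genes that exceeds the replicate spread was 1.96 times the pooled replicate SD of log2(CPM + 1), taken over genes with a mean of at least 100 CPM, for a difference of means of 2 libraries. Folds between members of a cluster come from means of log2(CPM + 1), and folds between summed clusters from log2 ratios of CPM without an added count, averaged over the libraries.

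Ratios of replicate 2 to replicate 1 used edgeR TMM factors of 0.952 and 1.05. The biological coefficient of variation (BCV) was estimated in edgeR with an intercept-only design on the 455 genes with at least 10 reads summed. Single genes were compared with a two-sided exact conditional binomial test with Benjamini-Hochberg adjustment over the same 455 genes, which takes in counting error only. The edgeR quasi-likelihood test could not be used, since 1 library per side leaves no residual degrees of freedom. The edgeR exact test with a BCV fixed at 0.2 was run as an alternative. For each gene list with at least 3 members of 10 reads or more, the median log2 ratio was ranked among 10000 random lists of the same size, matched on mean expression by deciles, two-sided and adjusted over the 20 lists tested. A Pearson chi-square test over genes with expected counts of at least 5 asked whether the libraries differed by more than sampling noise.

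The genes named follow a rule set before the data were examined. It takes the 15 genes of highest mean CPM, and up to 4 members of highest mean CPM of each of 22 fixed lists, or only the highest where all members lie under 10 CPM. It also takes the 5 largest and the 5 smallest log2 ratios among genes with a mean of at least 100 CPM and an adjusted binomial p under 0.05, and the highest and lowest member of each of 18 genomic clusters. The lists cover the let-7, miR-17, miR-30 and miR-200 families, the Hox loci, the X-linked Mir322 and Mir503 cluster, the imprinted Dlk1-Dio3, Mest, Igf2, Gnas and H19 loci, the Sfmbt2 intron and the sensory epithelium cluster. The others are marker lists for adult kidney, endothelium, stroma, erythroid cells, leukocytes, striated muscle, neurons, liver, pancreas, gonad and adrenal, pluripotent cells, and hypoxia, p53 and ciliated cells. Genes outside the rule are said to be chosen after their values were seen.

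The alternatives tried were each library alone, reads on either strand, DESeq2 size factors, library totals, other minimum counts, other pseudocounts and the edgeR exact test. A 20-nt shared stretch, a comparison limited to genes without shared sequence and an edgeR exact test with a BCV trended on abundance were added after the data were seen. The gene test was tested on data simulated for the 455 genes with counting error only, without spread between libraries. Of genes simulated at 2-fold it called 74 of 98 (75.5%), at 4-fold 90 of 97 (92.8%), and of unchanged genes 12 of 244 (4.92%). These rates do not hold where libraries differ by more than counting error, as these do. Simulated BCVs of 0.1, 0.2 and 0.4 were estimated as 0.104, 0.195 and 0.404. Of 200 simulated lists of 6 members, 92.0% were called at a shift of 0.5 log2 and 4.0% without a shift. Lists were called there at p under 0.05 without adjustment. The simulated ratios were independent between genes, with the same spread at every abundance. These rates therefore do not describe the adjusted test on the real lists. Tools were Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, R 4.3.3, edgeR 4.0.16 and DESeq2 1.42.0.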

Results

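MicroRNAs were sequenced from kidneys of mouse embryos at embryonic day 16.5, a stage at which nephrons are still being formed. Per the labels, the 2 libraries are biological replicates 1 and 2, made from separate tissue samples of pooled kidneys that carry the same donor record. How far the pools are independent is therefore not settled, and the spread between libraries may be partly technical. Reads assigned to microRNA genes numbered 5317669 in replicate 1 and 7128703 in replicate 2, and fell on 618 and 658 of the 1973 annotated genes. Levels are given as the mean ± SD of both libraries (n = 2), in percent of the reads assigned to microRNA genes or as counts per 1000000 of them (CPM). Positions are on mm10.

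The kidney profile was led by Mir10a, a microRNA gene of the Hoxb locus, which held 15.5% ± 1.36 of the reads. Mir335, in an intron of the imprinted gene Mest, followed with 6.58% ± 0.620, and Mir10b, in introns of Hoxd3 and Hoxd4, with 6.14% ± 0.318. Next came 2 members of the let-7 family, which marks differentiating tissue. Mirlet7g, in an intron of Wdr82, held 5.57% ± 0.0235, and Mirlet7i held 5.23% ± 0.289. Mir126a, the endothelial microRNA that overlaps an exon of Egfl7, held 5.21% ± 0.0762, and Mir322, a homologue of human miR-424 on the X chromosome, held 4.10% ± 0.150. The smooth muscle microRNA gene Mir143 held 3.04% ± 0.721. Mir10a lies on chromosome 11 from 96317165 to 96317274, Mir335 on chromosome 6 from 30741299 to 30741396, Mir10b on chromosome 2 from 74726070 to 74726137 and Mir126a on chromosome 2 from 26591357 to 26591429.

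Below these, Mir99a (2.99% ± 0.0177), Mir26b (2.82% ± 0.0604), Mir17 (2.73% ± 0.0289) and Mir130a (2.66% ± 0.0594) lay close together. Mir196b, which overlaps an exon of Hoxa9, held 2.45% ± 0.195, Mir23b 2.39% ± 0.329 and Mir30e 2.14% ± 0.256. Mir23b and Mir30e, as well as Mirlet7g and Mirlet7i, each share an 18-nt stretch with another microRNA gene, so reads of theirs may be missing from the counts. The pooled replicate SD was 0.22 log2, so that genes 1.34-fold or more apart differed by more than the replicate spread. Mir10a exceeded Mir335 by more than this, while Mir335, Mir10b, Mirlet7g, Mirlet7i and Mir126a lay within it of each other. With 2 libraries an exact sign-flip test cannot go below p = 0.5.

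Few genes held most of the reads. The 10 most abundant genes held 57.1% ± 2.15 of them, with 58.7% (exact 95% interval 58.6 to 58.7) in replicate 1 and 55.6% (55.6 to 55.7) in replicate 2. The top 3 held 28.2% ± 2.30, the top 15 held 69.5% ± 1.73 and the top 50 held 91.2% ± 0.558. The libraries shared 9 of their 10 most abundant genes, 15 of 15 and 49 of 50. At 1 CPM or more in both libraries 387 genes were detected, of which 100 share sequence with another microRNA gene. At 100 CPM or more in both there were 172, at 1000 or more 77, and at 10000 or more 21.

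MicroRNA genes of the Hox loci, which lie among the genes that set position along the body axis, held 24.6% ± 1.89 of the reads, the largest share of the 22 lists. This rank rests on Mir10a, since with its reads left out the list held 10.9%, below the 16.5% of the let-7 family. All 6 measured members were detected. After Mir10a, Mir10b and Mir196b came Mir615, in an intron of Hoxc5, at 3346 ± 143.8 CPM, and the other 2 members, which share sequence with another microRNA gene, lay below it. The let-7 family held 13.9% ± 0.0543 over 10 measured members. After Mirlet7g and Mirlet7i came Mirlet7d at 15530.0 ± 1642 CPM and Mir98, in an intron of Huwe1, at 8463 ± 92.5 CPM. Of the 10 members, 8 share sequence with another gene, so the share of the family is uncertain. Its rank below the Hox-locus list is uncertain for the same reason, also with Mir10a kept.

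Proliferation-linked microRNAs of the miR-17 family clusters held 6.13% ± 0.0947, with 15 of 15 members detected. Of the 15 members 4 share sequence with another microRNA gene, so this share is uncertain. Mir17 and Mir20a of the founding cluster reached 27319 ± 289 and 10265 ± 289 CPM, and Mir93 and Mir106b, within the replication gene Mcm7, reached 9574 ± 266 and 6105 ± 527 CPM. The X-linked Mir322 and Mir503 cluster held 4.85% ± 0.00427, most of it from Mir322, followed by Mir351 at 5760.2 ± 1292 CPM, Mir503 at 852 ± 176 CPM and Mir542 at 711 ± 41.8 CPM. Of the 5 measured members of this cluster, 1 shares sequence with another microRNA gene.

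Imprinted loci, expressed from 1 parental allele, contributed through several regions. The Mest, Gnas, Igf2 and H19 loci together held 7.26% ± 0.592. Besides Mir335, these were Mir296 at 3745 ± 63.2 CPM and Mir298 at 2113 ± 117 CPM of the Gnas locus, and Mir483, in an intron of Igf2, at 806 ± 105 CPM. The Dlk1-Dio3 locus held 1.82% ± 0.141, and 45 of its 52 measured members were detected. Its highest members were Mir411 (3220.1 ± 263 CPM), Mir127 (2221 ± 240 CPM, antisense to Rtl1), Mir487b (2220.0 ± 115 CPM) and Mir379 (1505 ± 153 CPM). Of the 52 members 7 share sequence with another microRNA gene, Mir411 and Mir487b among them, so the share of this locus is uncertain. The rodent-specific cluster in the Sfmbt2 intron held 0.435% ± 0.0144, led by Mir467d at 1323 ± 27.4 CPM, Mir467e at 1249 ± 17.3 CPM, Mir467c at 994 ± 213.7 CPM and Mir669o at 366 ± 5.26 CPM. All 27 measured members of that cluster share sequence with other genes, and 8 were detected.

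Among cell-type lists, stroma and smooth muscle held 8.01% ± 1.41, with 12 of 13 members detected. Mir143 and Mir23b led it, before Mir23a at 11173 ± 1532 CPM and Mir21a, in an exon of Vmp1, at 7664 ± 1080 CPM. The miR-30 family, which is abundant in adult kidney and needed for podocytes and nephron formation, held 4.20% ± 0.521. Mir30e reached 21388 ± 2557 CPM, Mir30a 15587 ± 2106 CPM and Mir30d 4707 ± 536 CPM, against 101 ± 1.01 CPM for Mir30c-1. Of the stroma list 8 of 13 measured members, and of the miR-30 family 5 of 6, share sequence, so both shares are uncertain. The epithelial miR-200 family held 2.65% ± 0.0343. Its highest members were Mir429 (15538 ± 298 CPM), Mir200b (4848 ± 40.8 CPM), Mir200c (4552 ± 34.3 CPM) and Mir200a (923 ± 55.7 CPM). The sensory epithelium cluster held 0.552% ± 0.0140, with Mir182 at 2377 ± 355 CPM, Mir183 at 2282 ± 208 CPM and Mir96 at 859 ± 8.09 CPM.

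The fixed list of genes enriched in the adult kidney held a small share. The list took 0.222% ± 0.00558, and most of that came from Mir203, known also from skin, at 1710 ± 74.3 CPM. Of its 8 measured members 3 share sequence with another microRNA gene, so the share is uncertain. The miR-30 family is not part of this list, so the share does not stand for all microRNAs abundant in adult kidney. Mir204, in an intron of Trpm3, reached 227 ± 2.00 CPM, Mir192 reached 164 ± 2.32 CPM and Mir194-2 reached 95.2 ± 11.4 CPM. Mir194-2 has a copy in the genome, Mir194-1, with which it shares sequence.

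Blood-cell markers were detected. The leukocyte list held 0.342% ± 0.0706 over 4 measured members, most of it from Mir342, in an intron of Evl, at 2802 ± 637 CPM. Then came Mir223 of myeloid cells at 367 ± 43.1 CPM, Mir155 at 228 ± 18.7 CPM and Mir150 of lymphocytes at 19.4 ± 7.72 CPM. Mir142 of blood cells, also on the list, has no row, so the share and the order leave it out. The erythroid list held 0.0373% ± 0.00857, with Mir451a at 274 ± 59.7 CPM, Mir144 at 88.1 ± 24.4 CPM and Mir486 at 10.8 ± 1.65 CPM. Mir486 shares sequence with another microRNA gene, so its level and the share of the list are uncertain.

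The hypoxia, p53 and ciliated-cell list held 0.105% ± 0.0227, from Mir34c at 484 ± 41.5 CPM, the hypoxia-induced Mir210 at 286 ± 26.0 CPM, Mir449a of multiciliated cells at 142.9 ± 145.2 CPM and the p53 target Mir34a at 118 ± 9.59 CPM. The pancreas list held 0.0816% ± 0.0247, from Mir375 at 702 ± 234 CPM, Mir7-1 at 58.3 ± 1.87 CPM, Mir7b at 46.8 ± 15.7 CPM and Mir7-2 at 6.80 ± 1.10 CPM. Neuronal genes held 0.0706% ± 0.00322, with Mir132 at 364 ± 22.2 CPM, Mir137 at 105 ± 18.3 CPM, Mir128-1 at 67.2 ± 8.56 CPM and Mir212 at 37.1 ± 1.35 CPM. Striated muscle genes held 0.0315% ± 0.00155, from Mir206 at 277 ± 14.1 CPM, Mir208b at 20.5 ± 4.99 CPM, Mir499 at 8.53 ± 0.165 CPM and Mir208a at 5.09 ± 1.84 CPM. Of the neuron list 13 of 16 measured members, of the muscle list 4 of 10 and of the pancreas list 2 of 7 share sequence. The same holds for 4 of 12 in the pluripotent list, so these sums are uncertain. Liver Mir122 stood at 191 ± 27.6 CPM. The pluripotent list held 0.00304% ± 0.00134 and the gonad and adrenal list 0.00180% ± 0.000119, with Mir294 at 5.50 ± 4.32 CPM and Mir741 at 9.22 ± 3.72 CPM as their highest members.

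**Figure D1:**
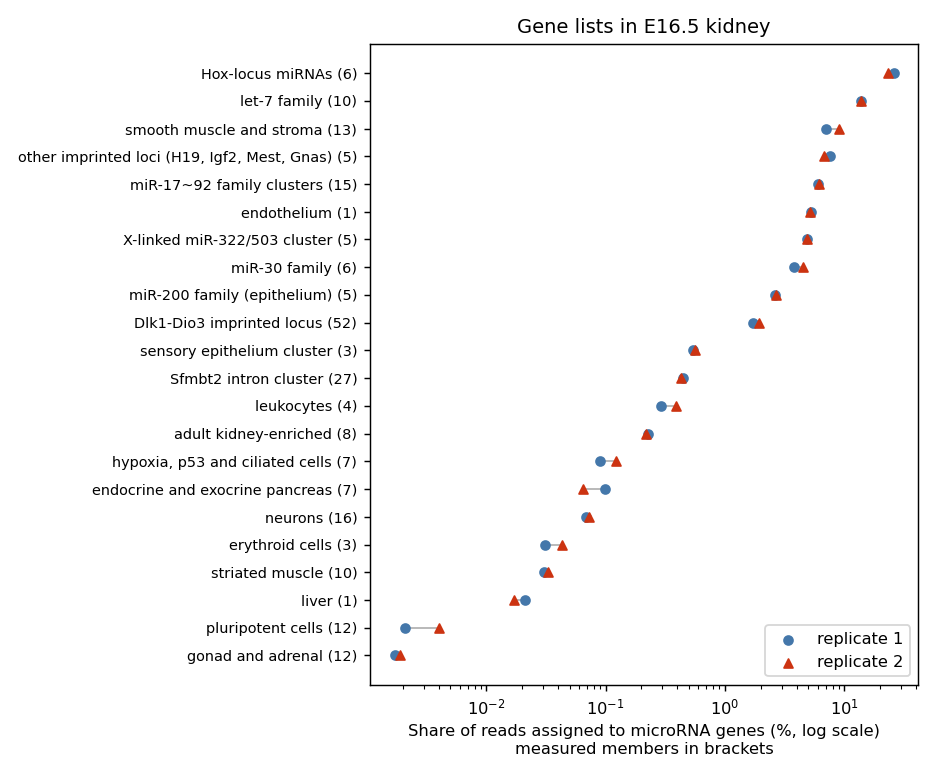
Share of reads assigned to microRNA genes held by each of the 22 gene lists, in percent on a log scale, with a circle for replicate 1 and a triangle for replicate 2 and the number of measured members in brackets. The Hox-locus list lies highest with 24.6% on average, and the pluripotent list shows 0.00209% in replicate 1 and 0.00398% in replicate 2.

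Genes of a cluster transcribed together stood at different levels. Folds between members are taken on log2(CPM + 1), so they differ from the ratio of the mean CPM values, most of all where the lower member has few reads. In the cluster that runs from Mir17 to Mir92-1, Mir17 stood 1968-fold above Mir19b-1, which was counted at 13.0 ± 2.11 CPM. Mir143 stood 66.9-fold above Mir145a (456 ± 135 CPM), Mir30e 209-fold above Mir30c-1, Mirlet7d 68.0-fold above Mirlet7a-1 (228 ± 33.5 CPM), and Mir214 64.6-fold above Mir199a-2 (58.4 ± 9.46 CPM). In the other clusters, Mir322 stood 194.1-fold above Mir450b, Mir23a 76.0-fold above Mir24-2, Mir106a 67.0-fold above Mir19b-2 and Mir30d 48.0-fold above Mir30b. Mir429 stood 16.8-fold above Mir200a, Mir93 15.7-fold above Mir25, Mir23b 12.7-fold above Mir27b, Mir200c 6.82-fold above Mir141 and Mir99b 5.06-fold above Mir125a. The narrowest ranges were those of Mir215 over Mir194-1 (3.97-fold), Mir451a over Mir144 (3.11-fold), Mir182 over Mir96 (2.75-fold) and Mir192 over Mir194-2 (1.72-fold). All 18 folds exceeded 1.34-fold. That value was set for a pair of genes from those at 100 CPM or more. The folds here take the highest and lowest member, so in larger clusters exceeding it is partly built in. Members with few reads also spread more, with a log2 SD of 0.82 for Mir106a over Mir19b-2. In 11 of the 18 clusters the lowest member shares an 18-nt stretch with another microRNA gene, so the fold is uncertain there.

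Summed over members, the Mir17 cluster (44104 ± 46.4 CPM) stood 47.4-fold above its X-linked paralogue, the Mir106a cluster (932 ± 43.6 CPM), and 2.71-fold above the Mir106b cluster (16289 ± 857 CPM). Of the epithelial clusters, that of Mir200b and Mir429 stood 4.08-fold above that of Mir200c and Mir141. The Mir23b cluster stood 2.25-fold above the Mir23a cluster, and the smooth muscle cluster of Mir143 and Mir145a stood 7.85-fold above that of Mir199a-2 and Mir214. Each of these 5 folds exceeded 1.34-fold, which was set for single genes. The fold between the Mir23b and Mir23a clusters is uncertain, since all measured members of both, 2 and 3, share sequence. In the Mir17 and the Mir106a cluster 2 members each share sequence, and in the Mir199a-2 cluster 1 does. The folds that involve these clusters are therefore uncertain too. Only the fold between the epithelial clusters rests on members that share no sequence.

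**Figure D2:**
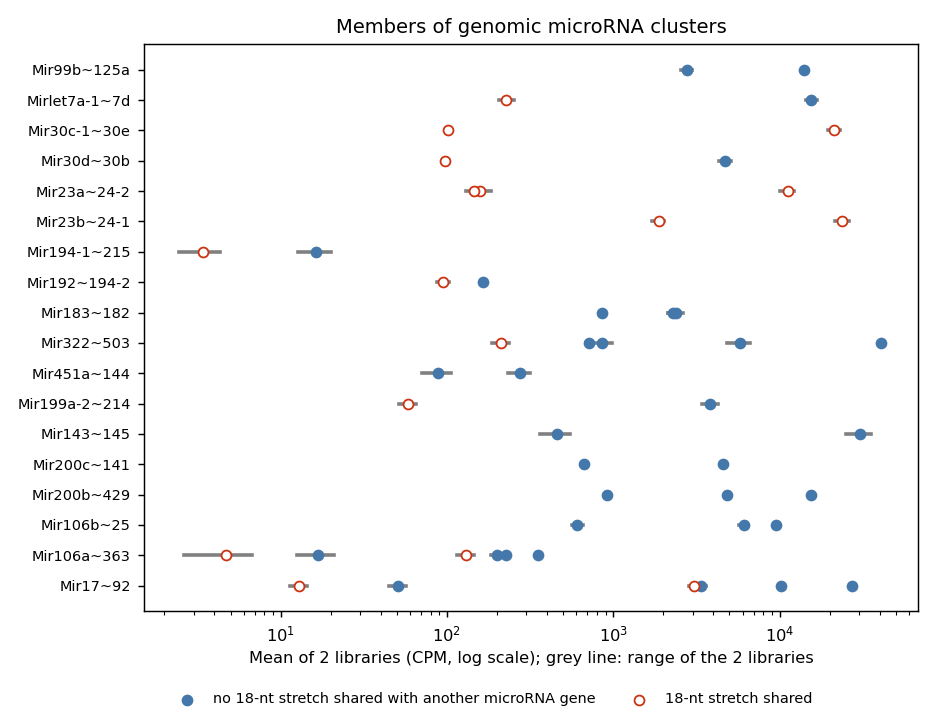
Mean level of each measured member of the 18 genomic clusters, in CPM on a log scale, with a grey line for the range of the 2 libraries. Filled points share no 18-nt stretch with another microRNA gene and open points do; Mir17 lies at 27319 CPM and Mir19b-1 at 13.0 CPM in the lowest line of the plot.

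The libraries were then compared with each other to see how far the pools differed. Mir449a, of multiciliated cells, stood out among abundant genes at 40.2 CPM in replicate 1 and 246 CPM in replicate 2, a log2 ratio of 2.46 with a counting error of 0.10. Next higher in replicate 2 were Mir181b-2 (0.51), Mir669c (0.51), Mir541 (0.47) and the smooth muscle gene Mir145a (0.47). Lower in replicate 2 were Mir375, abundant in endocrine cells (-0.84), Mir6236 (-0.66), Mir467c (-0.59), neuronal Mir137 (-0.50) and Gm23935 (-0.45). Each of these 10 genes had an adjusted p of 3.8e-08 or less in the exact binomial test, which counts reads only. Of the 181 genes with a mean of at least 100 CPM, 177 (97.8%) lay within 1.5-fold, and only Mir449a reached 2-fold.

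In the binomial test 153 of 455 genes passed an adjusted p of 0.05, 72 higher and 81 lower in replicate 2. TMM scaling shifted all log2 ratios by 0.14 relative to library totals, with which 152 of 193 passing genes (78.8%) were higher, against 47.1% with TMM. Of these genes 16 differed by 2-fold or more. Besides Mir449a, the higher ones were Mir202, Mir293, Mir294, Mir302c, Mir547, Mir19b-2, Mir669h and Mir3088, and the lower ones were Mir6240, Mir1960, Mir2137, Mir5626, Mir6928, Mir7026 and Gm24245. Those outside the naming rule were listed after their values were seen. With the spread between pools set to a BCV of 0.2 in the edgeR exact test, 3 genes passed. These were Mir449a (adjusted p = 1.2e-05), Mir202 with 6 and 63 reads (log2 ratio 2.72, adjusted p = 0.00775) and Mir6240 with 172 and 76 reads (-1.74, adjusted p = 0.0304). With a BCV trended on abundance, a setting chosen after the data were seen, the same 3 genes passed the edgeR exact test, Mir202 closest to the threshold (adjusted p = 0.0418).

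Across the 387 detected genes the libraries correlated with a Pearson r of 0.995 and a Spearman rho of 0.990 on log2(CPM + 1). The BCV was 0.142 over all tested genes, with a median of 0.125 on the abundance trend at 100 CPM or more and of 0.283 from 1 to 10 CPM. The median of gene-wise dispersions in DESeq2 gave 0.0295. A chi-square of 48547 on 430 degrees of freedom, 112.9 per degree, showed that the libraries differed by more than read sampling noise, so they are not 1 library given in duplicate. It does not show whether the pools were independent, since separate preparations of 1 pool can also differ by more than this.

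**Figure D3:**
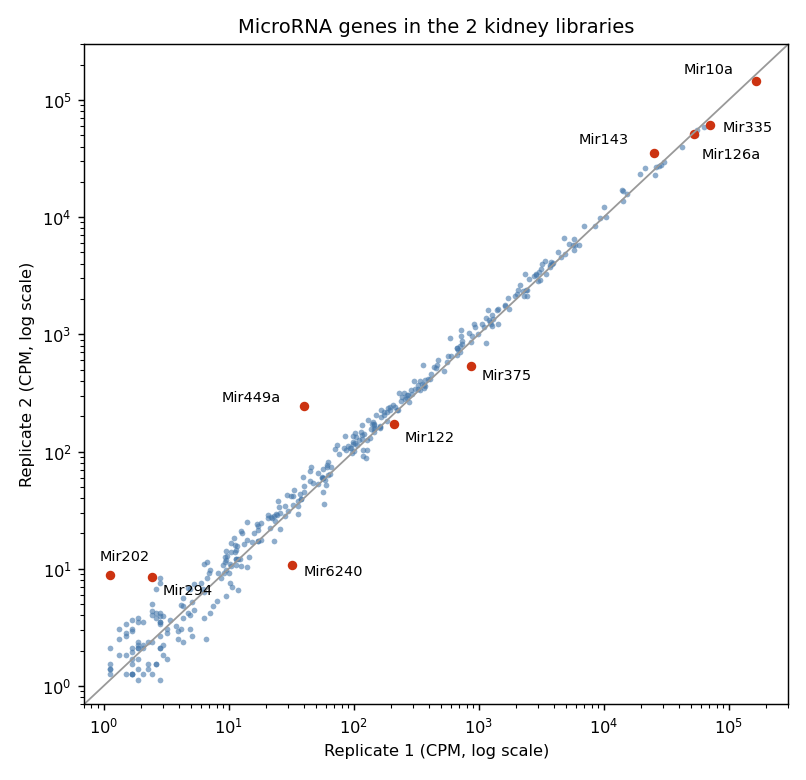
Level of each of the 387 detected genes in replicate 1 and replicate 2, in CPM on log axes, with the line of equal level. Most points lie along the line up to Mir10a, at 164308 and 145054 CPM, while Mir202, at 1.13 and 8.84 CPM, and Mir449a, at 40.2 and 246 CPM, lie above it.

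Of 20 lists tested for a joint shift, 5 lay outside the range of random matched lists. The random lists draw genes independently, while the X-linked list is 1 genomic cluster and the stroma and pluripotent lists hold members of clusters. Members transcribed together can move together, so the permutation p-values may be too small. The Hox-locus list was lower in replicate 2, with a median log2 ratio of -0.28 at percentile 0.15 of 10000 random lists (permutation, adjusted p = 0.0340), and 6 of its 6 members were lower. Mir10a stood at -0.32, Mir196b at -0.31 and Mir10b at -0.25. The stroma list was higher, with a median of 0.16 at percentile 99.6 (permutation, adjusted p = 0.0400). Of its 12 tested members, 8 were higher, among them Mir145a and Mir143 (0.35), and 1 was lower.

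The pancreas list was lower, with a median of -0.84 (permutation, adjusted p = 0.0400), from Mir375 and Mir7b (-0.84), 2 of 5 members. Mir7-1 stood at -0.08 and Mir7-2 at 0.18, and neither passed. The pluripotent list was higher, with a median of 1.04 (permutation, adjusted p = 0.0340), and 3 of 10 members passed. The X-linked Mir322 and Mir503 list had a median of 0.19 (permutation, adjusted p = 0.0400), with 3 members higher, among them Mir351 (0.32) and Mir503 (0.28), and Mir322 lower (-0.22). Its sum went the other way, at -0.14 with TMM, and was 48459.8 and 48520.2 CPM in the libraries. Adjusted over the list alone, 6 Hox-locus, 9 stroma, 2 pancreas, 3 pluripotent and 4 X-linked members passed, the same numbers as over all genes. None of the 5 shifts passed when all genes under 10 CPM were left out, both from the lists and from the random lists. By permutation, adjusted p was then 0.0567 for the Hox-locus, stroma and pancreas lists and 0.0816 for the X-linked list. The pluripotent list had too few members. The X-linked list lost no member, as its lowest, Mir450b, stood at 211 CPM, so only the random lists and the adjustment changed for it. The medians were then -0.28 for the Hox-locus, 0.15 for the stroma, -0.84 for the pancreas and 0.19 for the X-linked list.

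The other 15 lists had adjusted p from 0.171 to 0.981 by permutation. Among them, 6 of the 10 let-7 members were higher and 4 lower, and of the 47 tested Dlk1-Dio3 members 6 were higher, 5 lower and 36 did not pass. The leukocyte list had 2 of 4 members higher, Mir342 (0.32) and Mir150 (0.69), and the erythroid list 2 of 3, Mir451a (0.30) and Mir144 (0.43). The miR-200 family had 4 of 5 members lower, with a median of -0.13, but its share of library totals was 2.63% in replicate 1 and 2.68% in replicate 2, the other direction. The let-7 median (0.12) and sum (-0.15) also differed in sign with TMM. Adjusted over the list alone, 10 let-7, 11 Dlk1-Dio3, 3 leukocyte, 2 erythroid and 4 miR-200 members passed.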

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

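The tests on the strand opposite a gene row and on members of clusters with and without shared sequence were chosen after the results they examine were seen. The genes named for reads on the opposite strand were chosen by those reads.

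Reads on the strand opposite a gene row were not used in the report, yet 10 rows held at least 100 CPM of them in both libraries, far above the 3 reads that a count of 0 allows. On the strand of the reads, GENCODE M21 places a microRNA gene that has no row in the tables used here. The row Gm25301 on chromosome 18, from 61397813 to 61397925, held 10234 ± 583 CPM (n = 2) across from Mir378a, a gene in the Ppargc1b locus, a level that would rank 22 among all genes. The row Gm25927 held 5096 ± 510 CPM across from Mirlet7e, and the row Gm24083 held 2428 ± 198 CPM across from Mir191. In the imprinted Dlk1-Dio3 locus, Gm24321 held 1678 ± 218 CPM across from Mir409, Gm25252 held 791 ± 94.3 CPM across from Mir376a, Mir299b held 601 ± 72.8 CPM across from Mir299a, and Gm25750 held 206 ± 16.6 CPM across from Mir380. Mir497b held 649 ± 93.0 CPM across from Mir497, Mir142b held 446 ± 52.1 CPM across from Mir142 of blood cells, and Gm24111 held 160 ± 12.7 CPM across from Mirlet7f-1.

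Loss of strand information in the libraries is argued against, because in the 50 most abundant rows with no microRNA gene across from them the opposite strand held at most 0.000642% of the reads. Of all opposite-strand reads, 99.9% in each library lay in the 32 rows that overlap such a gene. These values are consistent with reads of the microRNA genes that have no row, as a hypothesis found and tested on the same data. No biological explanation was tested, since the series has 1 group.

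Reads mapping to several places made up 28.0% of replicate 1 and 25.3% of replicate 2, and enter no gene row. In the 8 clusters that hold both kinds of member, those that share an 18-nt stretch with another microRNA gene lay lower in 8 of 8. The median difference was -3.85 log2 (range -6.09 to -0.78, exact sign-flip p = 0.0078125, the smallest that 8 clusters can give). That p takes the clusters as independent and is too small. Among them are the paralogous Mir17 and Mir106a clusters, and those of the copies Mir194-2 and Mir194-1. Loss of reads from identical copies may account for the low counts of Mir19b-1, Mirlet7a-1 and Mir199a-2. It is argued against as the whole cause of unequal members, because members without shared sequence still differed by a median of 16.3-fold (2.75 to 532) over 10 clusters. This holds only as far as an exact 18-nt stretch in annotated microRNA genes marks the copies. Copies elsewhere in the genome and near-identical sequences were not covered. Differences in processing, stability or capture of single microRNAs stay open and were not tested.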

How the results depend on the processing

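The named-gene rule, the lists, the tests of the report except the trended BCV and all but 3 alternatives were chosen before the data were examined; the comparison of cluster members with and without shared sequence, the 20-nt stretch, the comparison limited to genes without shared sequence and the trended BCV were added after. No paired analysis was possible because the series has a single group. With each library alone, 418 to 423 genes were detected and the top 10 genes held 55.6% to 58.9% of the reads. The top 10 share was 52.5% when the most abundant gene was left out. The Pearson r was 0.996 over all genes, 0.997 at 100 CPM or more and 0.994 with a pseudocount of 0.1, and rho was 0.904 over all genes and 0.995 at 100 CPM or more. The BCV was 0.0295 as a DESeq2 median of gene-wise dispersions; the cause was not tested. Genes differing by 2-fold fell from 16 to 1 at a mean of at least 100 CPM, where fewer genes are tested, and to 3 in the edgeR exact test with a BCV of 0.2, which adds spread between pools, and to the same 3 with a BCV trended on abundance. Without a filter on low counts there were 16, of which 13 were shared with the 16 reported, and Mir2137, Mir3088 and Mir5626 no longer passed. The list shifts fell from 5 to 0 at a mean of at least 10 CPM, a filter that also took genes out of the random lists. The medians of the Hox-locus, pancreas and X-linked lists did not move. The X-linked list kept all its members, so its change came from the random lists and the adjustment. The pluripotent list had too few members, and for the other lists the cause was not tested. The X-linked list also missed the threshold with reads on either strand (adjusted p = 0.0536). Limited to genes without shared sequence, 13 genes differed by 2-fold. Of the named genes, 34 log2 ratios no longer passed in the edgeR exact test with either BCV and 1, that of Mir5626, with library totals. Shares moved by over 1 SD for 17 lists without the most abundant gene, where the let-7 family (16.5%) in place of the Hox-locus list (10.9%) held the largest, and for 5 lists with reads on either strand, as did 22 gene levels there. With library totals in place of TMM, 17 of the 153 passing genes and 7 of the 22 list sums changed sign, among them the sums of the miR-200 and X-linked lists, and 78.8% of passing genes in place of 47.1% were higher in replicate 2. The 2-fold genes and the medians of the 5 shifted lists kept their direction in each setting in which they could be computed. This was largely fixed in advance, since TMM scaling shifts all log2 ratios by only 0.14 and the edgeR exact tests reused the same ratios. The fold between genes that exceeds the replicate spread ranged from 1.34 to 1.38, 10 lists held at least 1% of the reads in every setting run, and the shared members lay lower in 7 of 7 clusters with a 20-nt stretch. Depth limits genes near 1 CPM, which rest on few reads.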

Other observations

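The sums over genes, the tests with a trended BCV and the interval of the GC trend were chosen after the results were seen, as was the use of the adjusted p of Mir449a, Mir202 and Mir294 against counting error; the exact binomial test, the edgeR exact test with a BCV of 0.2 and the removal of the GC trend were chosen before.

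Of the pancreas list, Mir375 and Mir7b had log2 ratios of -0.84 each between the libraries, while Mir7-1 stood at -0.08 (adjusted p = 0.637 in the exact binomial test) and Mir7-2 at 0.18 (adjusted p = 0.735 in the same exact test). Mir216a, Mir216b and Mir217, known from exocrine pancreas, had 15 and 9 reads, a log2 ratio of -1.30 (95% interval for counting error -2.68 to -0.02). Reads of the 4 Dlk1-Dio3 genes counted on the opposite strand would bring that locus to 21441 ± 1809 CPM (n = 2).

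Mir449a, Mir202 and members of the Mir290 cluster, known from pluripotent and germ cells, were higher in replicate 2. The Mir290 cluster had 46 and 172 reads, a log2 ratio of 1.34 (0.86 to 1.84). Counting error is argued against for Mir449a and Mir202, whose larger adjusted p was 0.00775 in the edgeR exact test with a BCV of 0.2 and 0.0418 with a trended BCV. Mir294 passed the exact binomial test (adjusted p = 0.00019), which takes each read as an independent molecule. It did not pass the edgeR exact tests (adjusted p = 0.549 and 0.885), so counting error is not decided for Mir294. Spread between pools stays open for each of these genes. The BCV of 0.2 was assumed, and the trended BCV came from the libraries compared. A larger share of gonad cells in pool 2 may account for Mir202, yet the other 11 members of the gonad list, of which Mir741 is highest at 9.22 CPM, had 85 and 71 reads, a log2 ratio of -0.83 (-1.30 to -0.35), while the Mir302 members stood at 0.22 (-0.23 to 0.68). A larger share of ciliated cells may account for Mir449a, yet Mir34b and Mir34c stood at 0.0431 (-0.03 to 0.12), and Mir449b and Mir449c had 3 and 8 reads. Both stay open, because other kidney cells can hold Mir34b and Mir34c and because the members of the gonad list need not come from the same cells, and no biological explanation was tested with 1 group.

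Log2 ratios hardly followed the GC content of the precursors across the 455 genes (rho -0.03), so removing the trend moved little. The Hox-locus median was -0.28 before and -0.29 after (permutation, adjusted p = 0.0320). The stroma median was 0.16 before and after (permutation, adjusted p = 0.0350). At the precursor GC content of the members, the trend of the other genes was 0.02 for the Hox-locus list (bootstrap 95% interval -0.06 to 0.09). For the stroma list it was -0.00276 (-0.07 to 0.08). These values argue against a trend over precursor GC content as the cause of either shift. GC content of the shorter fragments that were read was not tested.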
